A study of Mus musculus with 62 samples.

How the data were processed

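RNA from soleus muscle of 62 mice was sequenced as stranded mRNA libraries, per the labels' protocols, and the groups (CAC, NCAC, Con) and weeks were taken from the labels. The TPM values were deposited by the authors, and the genome build was mm10, per the submitters' processing notes. The aligner and the quantification tool are not given in the sources used here. TPM adds to the same total in each library, so the values do not give the depth of a library, and no interval or detection limit was computed. The labels disagree on the strain: the sample entries name C57BL6/J and the design text athymic nude mice, and the protocol text mentions LLC cells, so the strain is not stated here.

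Of 47643 genes, the 13529 with at least 1 TPM in at least 5 samples were tested. Values were transformed to log2(TPM + 1) and fitted with limma 3.58.1 (R 4.3.3), with 1 mean per group for 12 groups, 1 spread per gene over all 62 libraries and an intensity trend in the moderation. Adjusted p values are Benjamini-Hochberg values within a comparison, and a gene passed at an adjusted p under 0.05. Fold changes of TPM are relative to the total of the library. The comparisons were each pair of treatments within each week, Con at 8 against 2 weeks, and the difference of the CAC effect between 8 and 2 weeks. These comparisons, the rule for named genes, 37 gene lists and the alternatives were chosen before the data were examined, except where the text says otherwise.

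Named genes were, for CAC against Con and CAC against NCAC at 8 weeks, the 10 largest rises and the 10 largest falls among genes past the threshold whose higher group mean was at least 5 TPM. For every other comparison they were the 3 largest of each. Up to 4 members of a discussed list with the smallest adjusted p were added, and a panel of 15 genes was named whatever its result. Predicted genes without a proper symbol were counted and not named, and some genes that the rule names are not reported here. The number of libraries in a direction counts those of the group named first that lie beyond the mean log2 value of the other. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 37 lists. The count adjusted over the list alone repeats the adjustment within the list. Positions are from GENCODE M21 (mm10), which placed 131 of 132 named genes (not Wbscr17) and gave a length for 96.7% of the tested genes.

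The procedure was tested on simulated independent genes with each group's spread, 200 of them changed. It found 86.6% to 98.5% of log2 changes of 1 and 41.8% to 68.7% of changes of 0.5. False calls numbered 4 to 55 at weeks 2, 4 and 6. At 8 weeks there were 152 for CAC against Con, 382 for NCAC against Con and 765 for CAC against NCAC, because the spread shared by all weeks is smaller than that of week 8. A fit of week 8 alone gave 6, 17 and 38. It found 83.6%, 82.1% and 70.1% of changes of 1 and 32.8%, 20.9% and 43.3% of changes of 0.5. Fits without week 8 gave 16 to 165 false calls at earlier weeks. Camera found only the shifted list of 37. In NCAC against Con at 4 and 6 weeks it passed 10 and 6 lists at the preset correlation (0 genes by limma).

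The alternatives were a pseudocount of 0.1, no filter on low values, median-of-ratios rescaling, a fit of the compared groups alone, the replicate number as a block, sample quality weights, and leaving out each library in turn. Chosen after seeing the data were the fits without week 8 and of week 8 alone, a fit without the 3 libraries with at least 500 TPM of Myh4, and the difference of the CAC effect between 6 and 2 weeks. Samples were treated as unpaired. Figures used matplotlib 3.10.9 (Python 3.11.15).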

Results

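Gene expression was measured by RNA sequencing in the soleus, a hindlimb muscle rich in slow oxidative fibres, of female mice. The animals had received melanoma cells that bring on cachexia, the wasting of body tissue that accompanies some tumours (group CAC), melanoma cells that do not (NCAC), or a mock injection (Con). Muscle was taken 2, 4, 6 and 8 weeks after the injection. Each of the 12 groups held 5 libraries, except CAC at 8 weeks with 7, which made 62 libraries, and the labels call the libraries of a group biological replicates. The values were transcript abundances in TPM, which keep no read depth, so the depth behind each value is unknown. A level of at least 1 TPM was reached by 11799 ± 129 genes (SD, n = 5) in Con at 2 weeks and by 12880 ± 201 genes (SD, n = 5) in Con at 8 weeks. Fold changes are on the log2(TPM + 1) scale and understate the change of low genes, and each adjusted p is from limma over 13529 tested genes unless a list is named.

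The 8-week libraries stood apart from the earlier ones in every treatment. The first principal component held 56.9% of the variance, and 16 of the 17 libraries of week 8 lay beyond all earlier libraries on it. NCAC replicate 2 of week 8 lay at 3.71, within the earlier range, whose highest score was 4.16. Transcripts of the mitochondrial genome took 37.8 ± 1.11% of the TPM (SD, n = 5) in Con at 2 weeks and 28.7 ± 5.95% (SD, n = 5) in Con at 8 weeks. Libraries of 1 group also differed more from each other at 8 weeks, where the lowest pairwise correlation across genes was 0.912 in CAC, against 0.98 in CAC at 2 weeks. Counts between treatments at week 8 are therefore given a second time from a fit of the week 8 libraries alone. Counts for the earlier weeks are given from a fit without them where that moved them by over 1.5 times.

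**Figure D1:**
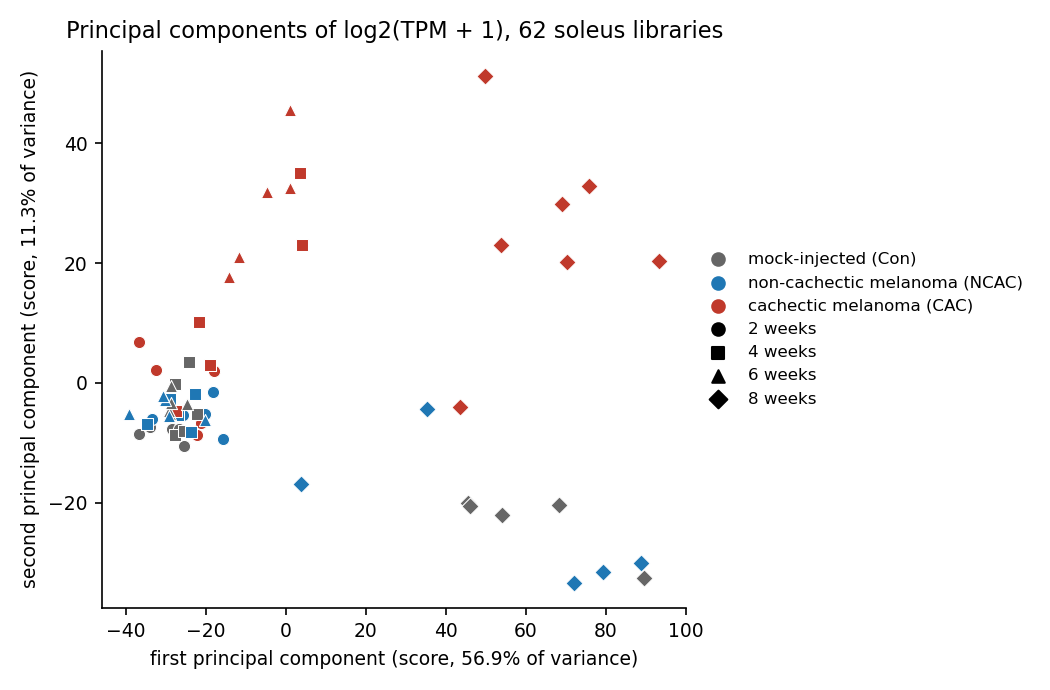
Scores of the 62 libraries on the first principal component (x axis, 56.9% of the variance) and the second (y axis, 11.3% of the variance) of log2(TPM + 1) values. Each point is 1 library, with colour for treatment and shape for week. The diamonds of week 8 lie to the right of the other libraries except NCAC replicate 2, and at 6 and 8 weeks most CAC libraries lie above those of Con and NCAC.

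The mock-injected animals at 8 and 2 weeks were compared to see how the muscle differed over time without a tumour. Markers of macrophages, adipocytes and connective tissue progenitors rose together. C1qa, a complement component made by macrophages, stood at 258 ± 81 TPM (SD, n = 5) at 8 weeks and 19.8 ± 5.85 TPM (SD, n = 5) at 2 weeks. Adipoq, the fat cell hormone adiponectin, stood at 569 ± 291 TPM (SD, n = 5) at 8 weeks and 29.8 ± 16.3 TPM (SD, n = 5) at 2 weeks. Of the macrophage markers 13 of 13 rose, with a median log2 fold change of 3.37, and 13 of 13 adipocyte markers (median 3.56) and 12 of 12 fibro-adipogenic progenitor markers (median 2.68) rose as well. All of these also passed when adjusted over the list alone. Of the 15 panel genes Serpina3n (2.62, SE 0.58, adjusted p = 1.13e-04) and Mt2 (2.39, SE 0.68, adjusted p = 0.00215) rose and Myh7 and Myh2 fell. Myh2, a fast myosin, fell by 0.97 (SE 0.39, adjusted p = 0.0268, 5 of 5). It lost its call without Con replicate 1 (0.0507), 3 (0.0536) or 5 (0.0569) of week 2 and replicate 2 (0.131) or 5 (0.0988) of week 8. By camera the adjusted p was 1.53e-09, 0.00166 and 3.26e-08 for the 3 lists, against adjusted p = 0.176, 0.481 and 0.176 with an estimated correlation. Fcer1g rose by 3.37 (SE 0.28), Cfd by 4.08 (SE 0.54), Smoc2 by 2.60 (SE 0.21) and Dpt by 3.54 (SE 0.31) on the log2 scale, each in 5 of 5 libraries with adjusted p of 5.69e-09 or lower. The largest rises were Nnat, the imprinted neuronatin gene, at 4.65 (SE 1.00, adjusted p = 7.39e-05), Mcpt4, a mast cell protease, at 4.53 (SE 0.41, adjusted p = 2.31e-13), and the chemokine Ccl8 at 4.31 (SE 0.57, adjusted p = 6.52e-09), each in 5 of 5 libraries.

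Most genes of the ribosomal protein and interferon response lists also rose at 8 weeks in mock muscle, and most sarcomere core genes fell. All 65 ribosomal protein genes rose (65 adjusted over the list alone, median 1.34, camera adjusted p = 2.74e-16, adjusted p = 0.342 with an estimated correlation). Among them was Rpl3 at 2.21 (SE 0.21, adjusted p = 1.84e-12, 5 of 5 libraries). After a trend on gene length was removed, which also takes out each library's overall level, the ribosomal protein median was 0.79. Rescaling without a length term gave 0.99. Of 28 interferon response genes 26 rose (27 adjusted over the list alone, camera adjusted p = 3.98e-05, adjusted p = 0.463 with an estimated correlation), among them the immunoproteasome subunit Psmb8 at 2.19 (SE 0.21, adjusted p = 1.75e-12) and B2m at 1.82 (SE 0.21, adjusted p = 2.44e-10), each in 5 of 5. Sarcomere core genes fell in 16 of 20 cases (16 adjusted over the list alone, median -0.77, camera adjusted p = 1.47e-13, adjusted p = 0.173 with an estimated correlation). Myom1, which links thick filaments, fell by 0.97 on the log2 scale (SE 0.18, adjusted p = 6.8e-06), and the giant spring protein gene Ttn fell by 1.22 (SE 0.24, adjusted p = 1.32e-05), each lower in 5 of 5. Slow fibre genes fell in 9 of 16 cases (14 rescaled, 9 adjusted over the list alone, camera adjusted p = 4.05e-08, adjusted p = 0.173 with an estimated correlation). Among them was Myh7, the slow myosin heavy chain, at -1.11 (SE 0.30, adjusted p = 0.00136, lower in 5 of 5). Mitochondrially encoded transcripts fell in 12 of 13 cases and genes of the TCA cycle and PGC-1 list in 18 of 22, with the same counts adjusted over each list alone and 5 and 18 in a fit of the compared groups alone (camera adjusted p = 2.26e-10 and 2.08e-12, adjusted p = 0.173 for both with an estimated correlation). The largest falls were Myl10 at -3.73 (SE 0.41), Igfn1 at -2.47 (SE 0.33) and the olfactory receptor gene Olfr78 at -2.41 (SE 0.16), each in 5 of 5 with adjusted p of 7.35e-09 or lower.

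Markers of further cell types moved in different directions in mock muscle. Of 14, 10, 10 and 15 neutrophil, erythroid, platelet and lymphocyte markers, 8, 6, 3 and 3 were tested. Of these, 6, 3, 2 and 2 rose and 0 fell by limma, also adjusted over each list alone. Rescaled, 2 erythroid and 1 lymphocyte markers rose. The camera adjusted p was 0.127, 0.74, 0.1 and 0.465, and for erythroid markers camera pointed down beside a median of 0.88. Schwann cell markers gave 2 rises and 6 falls among 11 (2 and 6 adjusted over the list alone, median -0.55, camera adjusted p = 2.37e-04, adjusted p = 0.33 with an estimated correlation). Smooth muscle and pericyte markers fell in 8 of 12 cases (8 adjusted over the list alone, camera adjusted p = 3.25e-06, adjusted p = 0.0135 with an estimated correlation). Among them was Myh11 at -1.34 (SE 0.20, adjusted p = 1.6e-07, lower in 5 of 5). Endothelial markers gave 3 rises and 1 fall among 12 (1 and 5 rescaled, 2 and 1 adjusted over the list alone, median 0.08, camera adjusted p = 0.149). Tenocyte markers gave 0 calls among 12 by limma (0 adjusted over the list alone, median 0.02, camera adjusted p = 0.0212, adjusted p = 0.562 with an estimated correlation). In all 7002 of 13529 genes rose and 1113 fell. Between 4 and 2 weeks no gene passed (0 by limma, 224 at unadjusted p under 0.05). Nor did any between 6 and 2 weeks (0 by limma, 319 at unadjusted p under 0.05), while 8118 passed between 8 and 6 weeks. Median-of-ratios rescaling moved the median gene by 0.29 and gave 4264 rises and 3933 falls. On that scale 13 macrophage, 12 adipocyte, 12 fibro-adipogenic and 61 ribosomal protein genes still rose, and 20 sarcomere core genes fell.

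At 2 weeks the cachectic tumour was compared with the mock injection to find early differences. Stat3, the transcription factor that interleukin-6 family cytokines activate, rose to 33.5 ± 8.07 TPM (SD, n = 5) in CAC, against 19.5 ± 1.13 TPM (SD, n = 5) in Con and 20.4 ± 1.23 TPM (SD, n = 5) in NCAC. The log2 fold change from Con was 0.72 (SE 0.13, adjusted p = 0.0175, limma), with 5 of 5 CAC libraries above the Con mean. It was the single gene past the threshold, with 435 at unadjusted p under 0.05, and lies on chromosome 11 between 100885098 and 100939540 (mm10). Of the 21 measured genes of the acute phase and STAT3 list, 1 rose over all genes (0 by limma without week 8) and 6 rose adjusted over the list alone (median 0.32, camera adjusted p = 9.96e-06, adjusted p = 0.695 with an estimated correlation). Tenocyte markers, genes of tendon cells, had a median of -0.85, with 0 of 12 past the threshold by limma (0 adjusted over the list alone, camera adjusted p = 3.24e-16, adjusted p = 0.113 with an estimated correlation). CAC replicates 2 and 4 stood apart in it, at medians of -2.78 and -2.60 from the Con mean, against 0.14 to 0.38 in the other CAC libraries and -1.69 in Con replicate 4. Replicate 4 also held 1013 TPM of the fast myosin Myh4, against 13.29 to 28.64 TPM in the other CAC libraries. The list median was -0.36 without CAC replicate 2, -0.43 without CAC replicate 4 and -1.29 without Con replicate 4. The Stat3 call was lost without Con replicate 1 (adjusted p = 0.0697), 2 (0.0504), 4 (0.142) or 5 (0.0543), without CAC replicate 3 (0.421) or 4 (0.238), and without week 8 (0.0563). The count rose to 2 genes without CAC replicate 1 or 5.

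CAC and NCAC at 2 weeks differed in 7 genes, all higher in CAC (1289 at unadjusted p under 0.05). Scx, a transcription factor of tendon cells, led them at 1.14 (SE 0.22, adjusted p = 0.0292, limma). Next came the glycosyltransferase gene Wbscr17 at 0.91 (SE 0.18, adjusted p = 0.0292) and Sbno2, a transcriptional coregulator, at 0.82 (SE 0.17, adjusted p = 0.0332), each higher in 5 of 5. Scx was the 1 tenocyte marker of 12 to pass (1 adjusted over the list alone), while the list had a median of -0.73 (camera adjusted p = 5.29e-05, adjusted p = 0.784 with an estimated correlation). That median was -0.28 without CAC replicate 2 (camera adjusted p = 0.0786) and -0.30 without CAC replicate 4 (0.0433). Against Con Sbno2, chosen after its values were seen, stood at 0.62 (SE 0.17, adjusted p = 0.637, higher in 5 of 5). The count was 0 without NCAC replicate 1, 3 or 5 or CAC replicate 3 or 4 (named genes at adjusted p 0.0883 to 0.257). It was 4 without NCAC replicate 4, 14 without CAC replicate 1 and 73 without week 8, and Sbno2 was lost without NCAC replicate 2 (0.0524). Rescaling gave 5 rises and 1 fall. NCAC and Con differed in Tbx15, a T-box transcription factor, at 0.58 (SE 0.10, adjusted p = 0.00646, limma, higher in 5 of 5; 547 genes at unadjusted p under 0.05). That call was lost without Con replicate 1 (adjusted p = 0.0705) or 4 (0.0755), without NCAC replicate 1 (0.0618) or 4 (0.0514), and after rescaling (0.0629). No panel gene passed at 2 weeks (0 of 15 by limma).

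At 4 weeks some acute phase and STAT3 genes rose in CAC. Hp, the acute phase protein haptoglobin (chromosome 8, 109575128 to 109579172), reached 287 ± 338 TPM (SD, n = 5) in CAC against 11.4 ± 5.31 TPM (SD, n = 5) in Con and 11.4 ± 7.62 TPM (SD, n = 5) in NCAC, and its CAC libraries ran from 17.9 to 768 TPM. It rose 11-fold (log2 3.46, SE 0.69, adjusted p = 0.00315, limma). Ccl8 rose 7.05-fold (log2 2.82, SE 0.57, adjusted p = 0.0038). The protease inhibitor Serpina3n rose 6.66-fold (log2 2.74, SE 0.58, adjusted p = 0.00708). Each rose in 5 of 5. CAC replicates 2 and 4 held 273 and 266 TPM of Serpina3n, against 10.4 to 27.3 in the others. Of the acute phase and STAT3 list 7 of 21 rose and 0 fell (14 and 0 without week 8, 14 and 0 adjusted over the list alone, median 1.09, camera adjusted p = 2.02e-20, adjusted p = 0.0408 with an estimated correlation). Its members included Stat3 at 1.23 (SE 0.13, adjusted p = 1.21e-08), its feedback inhibitor Socs3 at 2.73 (SE 0.34, adjusted p = 6.29e-07), the NF-kB cofactor Bcl3 at 1.30 (SE 0.21, adjusted p = 9.8e-05) and the oncostatin M receptor Osmr at 1.11 (SE 0.19, adjusted p = 2.7e-04), each in 5 of 5.

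Immediate early genes rose in 3 of 20 cases at 4 weeks (1 rescaled, 5 adjusted over the list alone, camera adjusted p = 8.7e-05, adjusted p = 0.742 with an estimated correlation). Among them was Junb at 1.69 (SE 0.31, adjusted p = 8.63e-04, 5 of 5). Nuclear-encoded respiratory chain genes had a median of -0.09 with 0 of 61 past the threshold by limma (1 lower without week 8, 0 adjusted over the list alone, camera adjusted p = 1.04e-09, adjusted p = 0.742 with an estimated correlation). The 3 largest falls were the crystallin genes Crybb1 at -0.82 (SE 0.20, adjusted p = 0.0253) and Cryba4 at -0.80 (SE 0.19, adjusted p = 0.0203) and the amidase gene Wdyhv1 at -0.43 (SE 0.10, adjusted p = 0.0284), each lower in 5 of 5. Over all genes 79 rose and 5 fell, and 462 (399 rises, 63 falls) passed without week 8. The count was 54 without Con replicate 1, 4 or 5, 30 without CAC replicate 2, 27 without CAC replicate 4 and 199 without CAC replicate 5. The calls for Hp (adjusted p = 0.0626), Ccl8 (0.066), Serpina3n (0.115), Crybb1 (0.115) and Wdyhv1 (0.104) were lost without CAC replicate 4. Without CAC replicate 2 the same happened to Serpina3n (0.122), Crybb1 (0.311), Cryba4 (0.264) and Wdyhv1 (0.297). The 3 falls were also lost without some Con libraries (adjusted p 0.0501 to 0.106).

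NCAC and Con did not differ at 4 weeks in any tested gene (0 by limma, 55 at unadjusted p under 0.05). CAC against NCAC gave 190 rises and 10 falls, 100 and 38 after rescaling, and 1277 genes without week 8. Hp rose by 3.58 (SE 0.69, adjusted p = 0.00167), Serpina3n by 2.80 (SE 0.58, adjusted p = 0.004) and Ccl8 by 2.62 (SE 0.57, adjusted p = 0.00714), each in 5 of 5. The acute phase and STAT3 list gave 9 rises of 21 (16 without week 8, 16 adjusted over the list alone, median 1.18, camera adjusted p = 1.59e-17, adjusted p = 0.0865 with an estimated correlation). Among them were Stat3 at 1.18 (SE 0.13), Socs3 at 2.40 (SE 0.34), Bcl3 at 1.39 (SE 0.21) and Osmr at 1.25 (SE 0.19), adjusted p of 2.29e-05 or lower and 5 of 5 each. Of 24 glucocorticoid and FoxO targets 2 rose (1 rescaled, 4 without week 8, 4 adjusted over the list alone, camera adjusted p = 0.00166, adjusted p = 0.678 with an estimated correlation). They were the translation inhibitor gene Eif4ebp1 at 1.15 (SE 0.26, adjusted p = 0.013, 5 of 5) and the metallothionein Mt2 at 2.55 (SE 0.68, adjusted p = 0.0391, 4 of 5). Against Con, Mt2 had a log2 fold change of 2.25 (SE 0.68, adjusted p = 0.129, 4 of 5), and it passed without CAC replicate 5 (0.00875) and without week 8 (0.0294). The falls included Tceal7 at -1.33 (SE 0.28, adjusted p = 0.00633) and Cryba4 at -0.84 (SE 0.19, adjusted p = 0.00974), each in 5 of 5. The count was 89, 91, 108, 128 and 102 without NCAC replicates 1 to 5, and 319, 42, 40 and 568 without CAC replicates 1, 2, 4 and 5. Without CAC replicate 2 the calls for Ccl8 (0.0509), Serpina3n (0.0615), Cryba4 (0.131), Eif4ebp1 (0.155) and Mt2 (0.346) were lost. Without CAC replicate 4 the same was true of Serpina3n, Eif4ebp1 and Tceal7 (each 0.0682), Ccl8 (0.084) and Mt2 (0.245). Mt2 was also lost without NCAC replicate 1 (0.0874), 2 (0.0601), 3 (0.0976) or 5 (0.0794) and after rescaling (0.0533).

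At 6 weeks CAC muscle differed from Con in 2941 rises and 328 falls. Serpina3n rose 28.3-fold by mean log2 values. Its mean level was 282 ± 155 TPM (SD, n = 5) in CAC, 8.4 ± 3.46 TPM (SD, n = 5) in Con and 6.33 ± 1.34 TPM (SD, n = 5) in NCAC. Mt2, which binds zinc and copper, rose 30.9-fold by mean log2 values. Its mean level was 622 ± 516 TPM (SD, n = 5) in CAC, 15.5 ± 2.73 TPM (SD, n = 5) in Con and 16.2 ± 7.06 TPM (SD, n = 5) in NCAC. Hp rose 40.3-fold (log2 5.33, SE 0.69, adjusted p = 1.79e-07, limma), and Serpina3n (log2 4.82, SE 0.58, adjusted p = 2.82e-08) and Mt2 (log2 4.95, SE 0.68, adjusted p = 8.85e-07) rose like it in 5 of 5. Kera, a corneal and tendon proteoglycan gene, fell from 24.5 ± 9.02 TPM (SD, n = 5) in Con to 4.82 ± 3.12 TPM (SD, n = 5) in CAC, and the fatty acid carrier gene Fabp3 fell by 1.05 on the log2 scale (SE 0.21, adjusted p = 3.02e-04, 5 of 5). The reads of Mt2 and Mt1, and those of the Serpina3 cluster, may be split between near-identical copies, so the share of each copy is uncertain. Rescaling moved the median of all genes by 0.15 and gave 911 rises and 910 falls, so the lists below carry their rescaled counts too. Without the week 8 libraries 4637 genes rose and 680 fell.

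Members of the acute phase, glucocorticoid and protein breakdown lists rose in part at 6 weeks. Of the acute phase and STAT3 list 16 of 21 rose (15 rescaled, 17 adjusted over the list alone, median 1.50, camera adjusted p = 1.16e-13, adjusted p = 0.14 with an estimated correlation). Among them were Stat3 at 1.42 (SE 0.13), Osmr at 1.81 (SE 0.19) and Socs3 at 2.93 (SE 0.34), adjusted p of 1.32e-08 or lower and 5 of 5 each. Glucocorticoid and FoxO targets rose in 13 of 24 cases (9 rescaled, 16 adjusted over the list alone, median 0.82, camera adjusted p = 1.97e-04, adjusted p = 0.692 with an estimated correlation). They included Mt1 at 3.45 (SE 0.52, adjusted p = 4.48e-06), the glucocorticoid receptor cochaperone Fkbp5 at 2.37 (SE 0.51, adjusted p = 9.09e-04), Errfi1 at 1.77 (SE 0.42, adjusted p = 0.00251) and the cell cycle inhibitor Cdkn1a at 1.42 (SE 0.37, adjusted p = 0.00476), each in 5 of 5. Atrophy ubiquitin ligases gave 5 rises and 1 fall among 16 (2 and 1 rescaled, 5 and 1 adjusted over the list alone, camera adjusted p = 0.6). The rises included Fbxo31 at 1.46 (SE 0.31, adjusted p = 7.19e-04) and Cblb at 0.69 (SE 0.16, adjusted p = 0.00198). Autophagy and lysosome genes rose in 12 of 24 cases (6 rescaled, 15 adjusted over the list alone, camera adjusted p = 8.05e-04, adjusted p = 0.602 with an estimated correlation). Among them were the lysosomal genes Ctsd at 0.59 (SE 0.09), Lamp1 at 0.36 (SE 0.07) and Lamp2 at 0.52 (SE 0.12), adjusted p of 0.00157 or lower and 5 of 5 each. Proteasome subunits rose in 19 of 31 cases and fell in 0 (1 rise and 2 falls rescaled, 23 rises adjusted over the list alone, camera adjusted p = 2.25e-04, adjusted p = 0.739 with an estimated correlation). Psmd4 rose by 0.68 (SE 0.13, adjusted p = 1.96e-04) and Psmd8 by 0.49 (SE 0.10, adjusted p = 6.81e-04), while rescaled values gave an adjusted p of 0.0627 for Psmd8 and 0.0737 for Lamp1.

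Some oxidative metabolism genes fell at 6 weeks, while most members of each list did not pass. Fatty acid oxidation genes fell in 12 of 26 cases (14 rescaled, 12 adjusted over the list alone, median -0.37, camera adjusted p = 4.68e-15, adjusted p = 0.14 with an estimated correlation). Among them were Hadhb at -0.88 (SE 0.19, adjusted p = 0.00114) and Eci1 at -0.64 (SE 0.14, adjusted p = 0.00139). Nuclear-encoded respiratory chain genes fell in 14 of 61 cases (35 rescaled, 12 adjusted over the list alone, median -0.20, camera adjusted p = 1.1e-24, adjusted p = 0.14 with an estimated correlation). Cox7a1, the muscle form of a cytochrome oxidase subunit, fell by 0.82 (SE 0.20, adjusted p = 0.00253), and the complex III gene Uqcrfs1 fell by 0.38 (SE 0.11, adjusted p = 0.01), each in 5 of 5. Mitochondrially encoded transcripts fell in 5 of 13 cases (8 rescaled, 8 adjusted over the list alone, camera adjusted p = 6.92e-10, adjusted p = 0.268 with an estimated correlation), and they took 33.1 ± 5.24% of the TPM in CAC (SD, n = 5) against 39.8 ± 1.03% in Con (SD, n = 5). Ribosomal protein genes rose in 25 of 65 cases (2 rescaled, 46 adjusted over the list alone, camera adjusted p = 2.95e-05, adjusted p = 0.876 with an estimated correlation). Among them was Rpl3 at 0.92 (SE 0.21, adjusted p = 0.00188, 5 of 5). Without the week 8 libraries 39 respiratory chain genes fell and 1 rose, 10 mitochondrially encoded transcripts fell and 60 ribosomal protein genes rose.

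At 6 weeks 7 of 8 tested neutrophil markers rose (5 rescaled, 7 adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.288 with an estimated correlation). Among them were Wfdc21 at 2.60 (SE 0.54, adjusted p = 6.67e-04), Il1r2 at 1.07 (SE 0.24, adjusted p = 0.00158) and Csf3r at 0.81 (SE 0.16, adjusted p = 3.07e-04), each in 5 of 5. Macrophage markers rose in 5 of 13 cases (1 rescaled, 8 without week 8, 7 adjusted over the list alone, camera adjusted p = 0.147) and adipocyte markers in 4 of 13 (1 rescaled, 4 adjusted over the list alone, camera adjusted p = 0.516). Tenocyte markers fell in 3 of 12 cases (4 rescaled, 3 adjusted over the list alone, median -0.65, camera adjusted p = 7.51e-06, adjusted p = 0.393 with an estimated correlation). These were Kera at -2.24 (SE 0.60, adjusted p = 0.00594), Cilp2 at -2.17 (SE 0.54, adjusted p = 0.00359) and Chad at -1.85 (SE 0.66, adjusted p = 0.0352), each in 5 of 5, and with Nrep at -2.12 (SE 0.38, adjusted p = 8.73e-05) Kera and Cilp2 were the 3 largest falls. Of the 15 panel genes 5 rose and 1 fell. The rises besides Serpina3n, Mt2, Fkbp5 and Cdkn1a included Lcn2, the acute phase lipocalin, at 2.54 (SE 0.46, adjusted p = 1.3e-04, 5 of 5), and the fall was Col1a1 at -1.53 (SE 0.57, adjusted p = 0.0424, 5 of 5). Not past the threshold were Trim63 (0.65, adjusted p = 0.191, 5 of 5), Fbxo32 (0.23, 0.635, 3 of 5) and Fbxo30 (0.33, 0.125, 4 of 5). The same held for Mstn (0.45, 0.394, 4 of 5), Pdk4 (0.03, 0.965, 3 of 5), Myh7 (0.30, 0.485, 3 of 5), Myh2 (0.00, 0.995, 3 of 5), Myh4 (0.23, 0.887, 4 of 5) and Gadd45a (0.19, 0.706, 4 of 5). Each has its log2 fold change, adjusted p and libraries in that direction. Fbxo30 passed without CAC replicate 5 (0.0413), and Trim63 without week 8 (0.0115). The count fell to 1293 without CAC replicate 1, 1838 without CAC replicate 4 and 2173 without Con replicate 2. The call for Uqcrfs1 was lost without CAC replicate 1 (0.0684), and those for Col1a1 (0.0695 to 0.148) and Chad (0.0678 to 0.104) without any of Con replicates 2, 3 and 4 or CAC replicates 1, 2 and 4.

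The non-cachectic tumour at 6 weeks gave no call against Con (0 by limma, 130 at unadjusted p under 0.05). CAC against NCAC gave 3328 rises and 432 falls, 1258 and 1358 after rescaling (shift of the median 0.15), and 5842 genes without week 8. Hp rose by 5.62 (SE 0.69, adjusted p = 4.3e-08), Serpina3n by 5.13 (SE 0.58, adjusted p = 5.28e-09) and Mt2 by 4.96 (SE 0.68, adjusted p = 7.23e-07). Nrep at -2.12 (SE 0.38, adjusted p = 6.15e-05), Kera at -1.96 (SE 0.60, adjusted p = 0.0121) and the clock output gene Dbp at -1.78 (SE 0.42, adjusted p = 0.00169) were the largest falls, each in 5 of 5. The acute phase and STAT3 list gave 17 rises of 21 (16 rescaled, 17 adjusted over the list alone, camera adjusted p = 4.09e-13, adjusted p = 0.208 with an estimated correlation). Among them were Stat3 at 1.43 (SE 0.13) and Osmr at 1.81 (SE 0.19). Proteasome subunits gave 22 rises of 31 (4 rises and 1 fall rescaled, 23 adjusted over the list alone, camera adjusted p = 2.57e-05, adjusted p = 0.573 with an estimated correlation). Among them was Psmd4 at 0.70 (SE 0.13). Respiratory chain genes fell in 17 of 61 cases (46 rescaled, 18 adjusted over the list alone, camera adjusted p = 3.12e-24, adjusted p = 0.208 with an estimated correlation). Among them was Cox7a1 at -0.97 (SE 0.20). Fatty acid oxidation genes fell in 11 of 26 cases (15 rescaled, 12 adjusted over the list alone, camera adjusted p = 4.09e-13, adjusted p = 0.229 with an estimated correlation), with Fabp3 at -0.96 (SE 0.21). Without the week 8 libraries 45 respiratory chain and 18 fatty acid oxidation genes fell, and 1 of each list rose. Circadian clock genes gave 4 rises and 2 falls of 18 (3 and 3 rescaled, 4 and 2 adjusted over the list alone, camera adjusted p = 0.217). Among them was the repressor Nfil3 at 2.69 (SE 0.48). Fbxo31 rose by 1.39 (SE 0.31), Fkbp5 by 2.35 (SE 0.51), Cdkn1a by 1.39 (SE 0.37) and Lcn2 by 2.44 (SE 0.46). Genes named after Dbp had an adjusted p of 0.00433 or lower, in 5 of 5. The count fell to 2031 without CAC replicate 1, and the call for Kera (adjusted p = 0.0633) was lost without it. Among genes that passed in both 6-week comparisons 2469 rose in both and 258 fell in both, against 723.5 and 10.47 for independent lists of these sizes. The comparisons share the CAC libraries, so part of the excess may come from them.

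**Figure D2:**
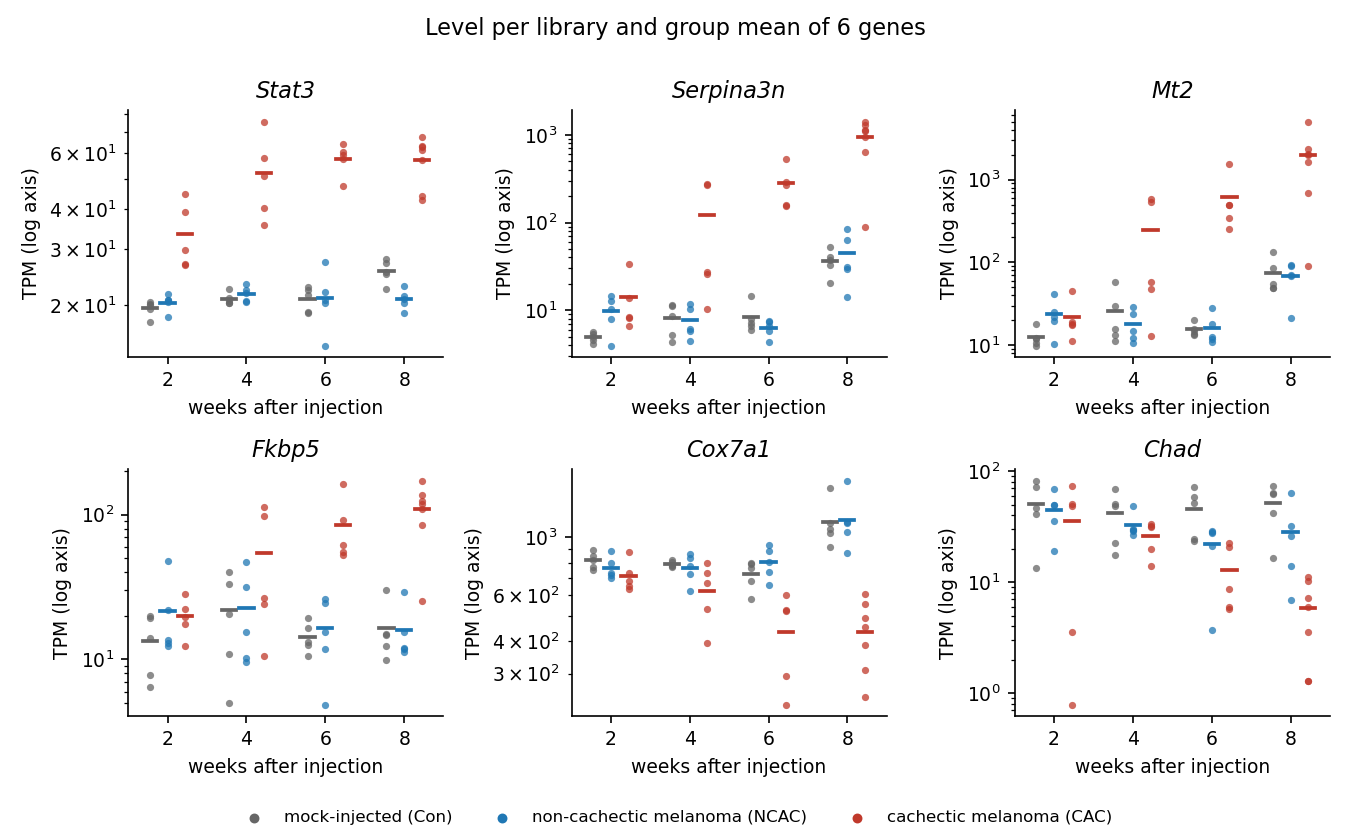
Levels of 6 genes in TPM (y axis, log scale) by weeks after injection (x axis). Each point is 1 library, each bar a group mean, with grey for Con, blue for NCAC and red for CAC. Serpina3n in CAC at 8 weeks ran from 88.7 to 1420 TPM, against 20.6 to 52 TPM in Con.

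At 8 weeks the cachectic tumour was compared with the mock injection at the latest time. Of the 10 largest rises 6 were members of the acute phase and STAT3 list. Serpina3n (chromosome 12, 104406729 to 104414329) reached 952 ± 457 TPM (SD, n = 7) in CAC, against 36.7 ± 11.4 TPM (SD, n = 5) in Con and 44.5 ± 28.7 TPM (SD, n = 5) in NCAC. Mt2 reached 1980 ± 1580 TPM (SD, n = 7) in CAC, against 74.6 ± 37.1 TPM (SD, n = 5) in Con and 68.7 ± 28.7 TPM (SD, n = 5) in NCAC. Cox7a1 (chromosome 7, 30184144 to 30186078) fell to 434 ± 131 TPM (SD, n = 7) in CAC, against 1140 ± 237 TPM (SD, n = 5) in Con and 1170 ± 292 TPM (SD, n = 5) in NCAC. Over all genes 2185 rose and 2021 fell, of which 251 and 236 changed at least 2-fold. In week 8 alone 854 rose and 576 fell, and 1427 of these 1430 genes were among the 4206. The 10 largest rises were Cxcl13, a B cell chemokine, at 4.82 (SE 0.63, adjusted p = 6.21e-08, limma), Serpina3n at 4.37 (SE 0.54, 1.7e-08), Mt2 at 4.18 (SE 0.63, 1.22e-06), Hp at 4.06 (SE 0.63, 2.44e-06). They also held the serum amyloid genes Saa1 at 3.91 (SE 0.54, 2.24e-07) and Saa3 at 3.44 (SE 0.84, 0.00127), Serpina3m at 3.89 (SE 0.36, 1.48e-11), Lcn2 at 3.59 (SE 0.43, 1.03e-08), Plac8 at 3.41 (SE 0.37, 1.15e-09) and the phospholipase gene Pla2g5 at 3.21 (SE 0.36, 2e-09). Each was higher in 7 of 7 libraries except Saa1 in 6 of 7, and in week 8 alone Saa3 did not pass (adjusted p = 0.122). CAC replicate 3 stood apart, with 88.7 TPM of Serpina3n, 89.4 TPM of Mt2 and 25.3 TPM of Fkbp5, against at least 642, 688 and 84.9 TPM in the other CAC libraries. It held 13070 TPM of the haemoglobin gene Hbb-bs, against 481.2 to 2157 TPM in the others. Saa1 has near-identical copies, so its share of their reads is uncertain.

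The 10 largest falls at 8 weeks were Nnat at -4.15 (SE 0.92, adjusted p = 4.74e-04), Nmrk2, a nicotinamide riboside kinase gene of muscle, at -3.63 (SE 0.57, 2.88e-06), the oxytocin receptor gene Oxtr at -3.31 (SE 0.50, 1.21e-06), Chad at -3.05 (SE 0.61, 1.29e-04). They also held Mfap4 at -2.95 (SE 0.41, 3.05e-07), Cilp2 at -2.61 (SE 0.50, 7.23e-05), Kera at -2.56 (SE 0.55, 3.38e-04), Retnla at -2.54 (SE 0.43, 8.25e-06), the eosinophil ribonuclease gene Rnase2a at -2.46 (SE 0.41, 8.43e-06) and Dact2 at -2.45 (SE 0.31, 2.5e-08). Each was lower in 7 of 7 libraries except Nnat in 6 of 7, and all 10 passed in week 8 alone. Nnat stood at 38.8 ± 68.9 TPM (SD, n = 7) in CAC, 195 ± 92.5 TPM (SD, n = 5) in Con and 288 ± 284 TPM (SD, n = 5) in NCAC. Chad, a cartilage and tendon matrix gene, stood at 5.82 ± 4.01 TPM (SD, n = 7) in CAC and 51.6 ± 22.7 TPM (SD, n = 5) in Con.

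At 8 weeks 18 of 21 genes of the acute phase and STAT3 list rose (15 in week 8 alone, 18 adjusted over the list alone, median 1.62, camera adjusted p = 4.91e-15, adjusted p = 0.183 with an estimated correlation). Among them were Osmr at 1.62 (SE 0.17, adjusted p = 8.49e-10) and Stat3 at 1.11 (SE 0.12, adjusted p = 1.52e-09). Glucocorticoid and FoxO targets rose in 20 of 24 cases (16 in week 8 alone, 22 adjusted over the list alone, median 1.05, camera adjusted p = 8.53e-11, adjusted p = 0.362 with an estimated correlation). Mt1 rose by 3.20 (SE 0.48, adjusted p = 9.84e-07), Fkbp5 by 2.60 (SE 0.47, 2.92e-05), Errfi1 by 2.26 (SE 0.39, 1.4e-05) and the kinase gene Sgk1 by 1.95 (SE 0.34, 1.42e-05), and these 6 genes were higher in 7 of 7. Atrophy ubiquitin ligases rose in 6 of 16 cases (3 in week 8 alone, 7 adjusted over the list alone, camera adjusted p = 0.0462, adjusted p = 0.803 with an estimated correlation). Fbxo31 rose by 1.78 (SE 0.28, adjusted p = 3.45e-06) and Cblb by 0.71 (SE 0.15, 2.11e-04), each in 7 of 7. Trim63 (MuRF1, which tags myofibrillar proteins; chromosome 4, 134315120 to 134329629) rose 2.82-fold (log2 1.50, SE 0.34, adjusted p = 6.56e-04, 7 of 7), with 419 ± 417 TPM (SD, n = 7) in CAC, 103 ± 32.7 TPM (SD, n = 5) in Con and 98.7 ± 42.1 TPM (SD, n = 5) in NCAC. Fbxo32 (atrogin-1) rose 1.9-fold (log2 0.93, SE 0.31, adjusted p = 0.0173, 6 of 7), and in week 8 alone neither passed (0.0824 for Trim63, 0.191 for Fbxo32). Autophagy and lysosome genes rose in 11 of 24 cases (2 in week 8 alone, 14 adjusted over the list alone, camera adjusted p = 8.01e-04, adjusted p = 0.803 with an estimated correlation). Among them were Lamp2 at 0.81 (SE 0.11, 1.39e-07, 7 of 7), the autophagosome gene Map1lc3b at 0.91 (SE 0.17, 4.47e-05, 6 of 7) and Bnip3l at 0.45 (SE 0.11, 9.33e-04, 7 of 7; adjusted p = 0.0792 in week 8 alone). Proteasome subunits gave 5 rises and 5 falls of 31 (1 and 7 rescaled, 1 and 0 in week 8 alone, 5 and 5 adjusted over the list alone, camera adjusted p = 0.895).

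Most respiratory chain genes and some fatty acid oxidation, TCA cycle and slow fibre genes fell at 8 weeks. Nuclear-encoded respiratory chain genes fell in 53 of 61 cases and rose in 0 (23 in week 8 alone, 57 adjusted over the list alone, median -0.43, camera adjusted p = 2.9e-24, adjusted p = 0.208 with an estimated correlation). Cox7a1 fell by 1.44 (SE 0.18, adjusted p = 3e-08), and the complex I and III genes Ndufb8 by 0.85 (SE 0.12, 3.72e-07), Ndufb3 by 0.50 (SE 0.07, 2.62e-07) and Uqcrh by 0.60 (SE 0.09, 8.11e-07), each lower in 7 of 7. Fatty acid oxidation genes gave 12 falls and 2 rises of 26 (1 and 0 in week 8 alone, 12 and 2 adjusted over the list alone, camera adjusted p = 0.00269, adjusted p = 0.803 with an estimated correlation). Among them were Fabp3 at -1.56 (SE 0.19, adjusted p = 1.3e-08) and Eci1 at -0.62 (SE 0.13, 2.83e-04; 0.0614 in week 8 alone). TCA cycle and PGC-1 genes gave 9 falls and 1 rise of 22 (1 and 0 in week 8 alone, 10 and 1 adjusted over the list alone, camera adjusted p = 0.00158, adjusted p = 0.803 with an estimated correlation). Among them were Mdh1 at -0.92 (SE 0.17, 4.78e-05) and Pdhb at -0.52 (SE 0.11, 1.49e-04; 0.0667 in week 8 alone), and these 4 genes were lower in 7 of 7. Slow fibre genes fell in 8 of 16 cases (3 in week 8 alone, 8 adjusted over the list alone, camera adjusted p = 0.0183, adjusted p = 0.803 with an estimated correlation). The slow myosin light chains Myl2 at -0.91 (SE 0.16, adjusted p = 1.33e-05, 7 of 7) and Myl3 at -0.74 (SE 0.14, 4.77e-05, 6 of 7; 0.0508 in week 8 alone), slow troponin Tnni1 at -0.81 (SE 0.17, 2.4e-04, 6 of 7) and phospholamban (Pln), which restrains the calcium pump, at -1.85 (SE 0.36, 9.95e-05, 6 of 7) were among them.

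Some matrix and connective tissue genes fell as well at 8 weeks. Extracellular matrix genes gave 17 falls and 1 rise of 32 (7 and 1 in week 8 alone, 18 and 3 adjusted over the list alone, median -0.91, camera adjusted p = 7.42e-04, adjusted p = 0.803 with an estimated correlation). Among them were Col5a3 at -1.94 (SE 0.30, adjusted p = 2.34e-06), fibrillin (Fbn1) at -1.95 (SE 0.36, 3.18e-05) and Col6a1 at -1.55 (SE 0.31, 1.45e-04). Tenocyte markers fell in 7 of 12 cases (6 in week 8 alone, 10 adjusted over the list alone, median -0.93, camera adjusted p = 8.01e-04, adjusted p = 0.803 with an estimated correlation). Among them was Tnmd at -2.05 (SE 0.55, adjusted p = 0.00312). Fibro-adipogenic progenitor markers fell in 6 of 12 cases (1 in week 8 alone, 7 adjusted over the list alone, camera adjusted p = 0.0224, adjusted p = 0.862 with an estimated correlation). Among them were Cd248 at -1.83 (SE 0.32, 1.87e-05) and Cd34 at -0.80 (SE 0.21, 0.00322; 0.152 in week 8 alone), and the 6 genes named here were lower in 7 of 7. Macrophage markers gave 1 rise and 1 fall of 13 (1 and 0 adjusted over the list alone, median -0.07, camera adjusted p = 0.906). Adipocyte markers gave 0 rises and 1 fall of 13 (0 adjusted over the list alone, camera adjusted p = 0.76) and Schwann cell markers 0 rises and 1 fall of 11 (1 fall adjusted over the list alone, camera adjusted p = 0.627), and none of these 4 calls was made in week 8 alone (0 by limma). Denervation response genes gave 5 rises and 3 falls of 16 (3 and 4 rescaled, 1 and 1 in week 8 alone, 5 and 4 adjusted over the list alone, camera adjusted p = 0.76). Among them were Runx1 at 0.90 (SE 0.16, 2.37e-05, 7 of 7), the muscle-specific kinase gene Musk at 0.87 (SE 0.26, 0.00813, 7 of 7; 0.0526 in week 8 alone) and Gadd45a at 1.01 (SE 0.31, 0.0102, 6 of 7; 0.0978 in week 8 alone).

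Of the 15 panel genes 8 rose and 1 fell at 8 weeks in CAC against Con. Fbxo30 (MUSA1), the rise not yet given, stood at 0.46 (SE 0.15, adjusted p = 0.0159, 7 of 7), and Col1a1 at -1.42 (SE 0.53, 0.0334, 7 of 7; 0.14 in week 8 alone). Not past the threshold were Cdkn1a (0.77, adjusted p = 0.0779, 6 of 7), Mstn (0.60, 0.189, 5 of 7), Myh4 (1.14, 0.361, 5 of 7), Myh7 (-0.33, 0.381, 3 of 7), Myh2 (0.17, 0.749, 4 of 7) and Pdk4 (0.12, 0.852, 4 of 7). Leaving out 1 library ended the call for Fbxo32 without Con replicate 2 (0.0728) or CAC replicate 1 (0.0828) or 6 (0.0549). It ended that for Fbxo30 without Con replicate 5 (0.0572) or CAC replicate 1 (0.0568). The call for Col1a1 ended without Con replicate 2 (0.114), 3 (0.052) or 5 (0.0626) or CAC replicate 1 (0.0869) or 6 (0.0938), and Cdkn1a passed without CAC replicate 3 (0.0208) or 4 (0.0437). From the genes higher at 4 weeks, 79 of 79 were also higher at 6 weeks (17.17 for independent lists). Both at 6 and 8 weeks 1337 genes rose and 247 fell (475 and 49 for independent lists, 10 opposite), and 74 genes passed in 1 direction at 4, 6 and 8 weeks (71 higher, 3 lower). With week 8 and the earlier weeks fitted apart, 374 of 399 genes higher at 4 weeks were higher at 6 weeks (136.8 for independent lists). On those fits 683 rose and 216 fell at both 6 and 8 weeks (292.7 and 28.95 for independent lists), and 140 rose and 23 fell at all 3 times.

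**Figure D3:**
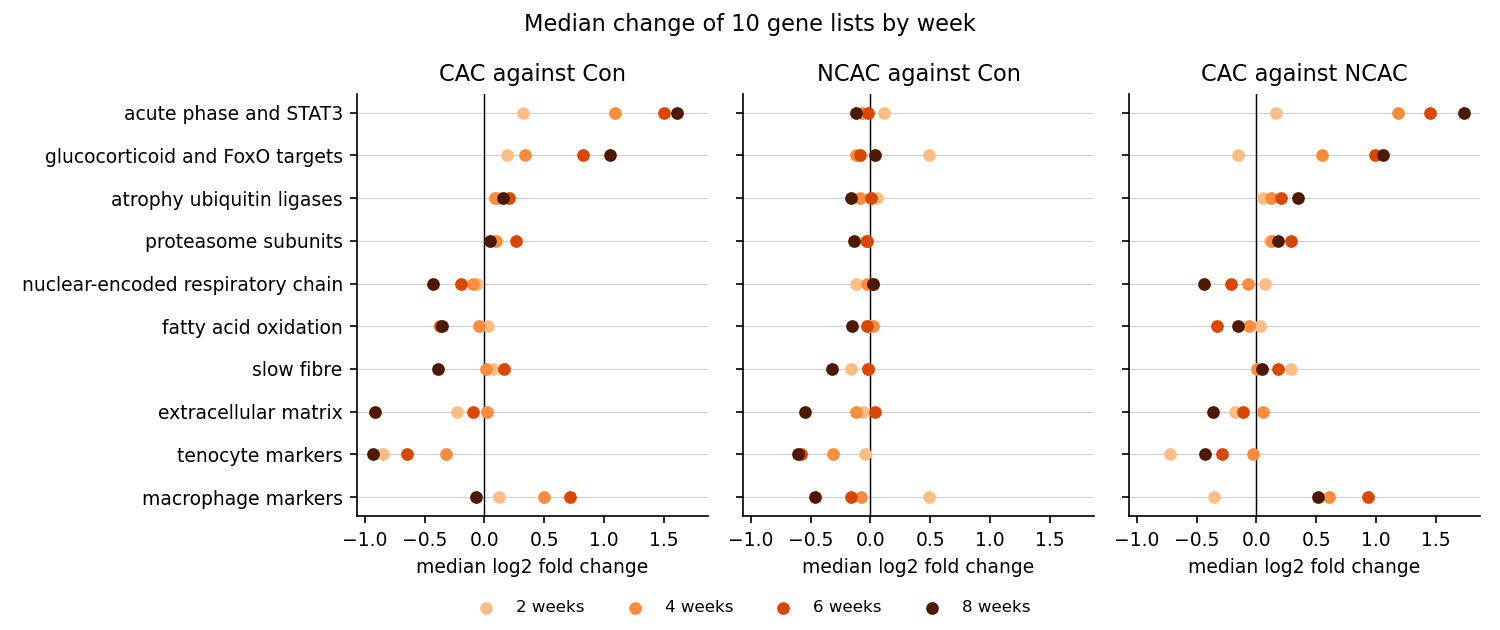
Median log2 fold change (x axis) of the tested genes of 10 lists (y axis), with 1 panel per comparison and 1 point per week. The acute phase and STAT3 median against Con was 0.32, 1.09, 1.50 and 1.62 at 2, 4, 6 and 8 weeks, and respiratory chain medians of CAC against Con lay below 0 in all 4 weeks.

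NCAC and Con at 8 weeks differed in 9 rises and 166 falls. The rises included mt-Atp8 and mt-Nd3, transcripts of the mitochondrial genome, at 0.92 (SE 0.21, adjusted p = 0.0321, limma, 4 of 5) and 0.68 (SE 0.13, 0.011, 5 of 5), and the non-coding Gt(ROSA)26Sor at 0.80 (SE 0.17, 0.0234, 5 of 5). Levels of mt-Atp8 were 17600 ± 7300 TPM (SD, n = 5) in NCAC and 8960 ± 3510 TPM (SD, n = 5) in Con. The falls were led by the osteocalcin gene Bglap2 at -1.49 (SE 0.40, 0.0467, 4 of 5), the chemokine Ccl2 at -1.24 (SE 0.32, 0.0429, 5 of 5) and Ubd at -1.17 (SE 0.27, 0.0334, 5 of 5). Mitochondrially encoded transcripts rose in 2 of 13 cases (2 adjusted over the list alone, camera adjusted p = 2.73e-12, adjusted p = 0.511 with an estimated correlation). Sarcomere core genes had 0 of 20 past the threshold by limma, and 5 lower adjusted over the list alone (median -0.51, camera adjusted p = 0.00808, adjusted p = 0.943 with an estimated correlation). Neither the acute phase and STAT3 list (0 of 21 by limma, median -0.12, camera adjusted p = 0.0814) nor the atrophy ubiquitin ligases (0 of 16, median -0.17, camera adjusted p = 0.711) had a member past the threshold, also adjusted over the list alone, and 0 of the 15 panel genes passed. In week 8 alone 0 genes passed by limma (1205 at unadjusted p under 0.05, smallest adjusted p = 0.516). Rescaling moved the median of all genes by -0.14 and gave 55 rises and 10 falls, 19 of them among the 175, and Bglap2 (0.11) and Ccl2 (0.103) did not pass. The count was 11, 93, 55, 612 and 44 without Con replicates 1 to 5, and 396, 664, 42, 8 and 1938 without NCAC replicates 1 to 5. Of the 6 genes mt-Nd3 kept its call without each library, while without NCAC replicate 4 those of mt-Atp8 (0.0896), Gt(ROSA)26Sor (0.0764), Bglap2 (0.118), Ccl2 (0.0886) and Ubd (0.0506) were lost. They were also lost without Con replicate 1 (Gt(ROSA)26Sor 0.0792, Ccl2 and Ubd 0.128), 2 (mt-Atp8 0.0607, Bglap2 0.0684, Ccl2 0.0704), 3 (mt-Atp8 0.0663, Bglap2 0.119) or 5 (Bglap2 0.0801, Ccl2 0.0583, Ubd 0.0521), and without NCAC replicate 3 (mt-Atp8 0.0618, Bglap2 0.112, Ccl2 0.0973, Ubd 0.086).

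At 8 weeks the 2 tumours were also compared. CAC gave 4793 rises and 1044 falls, and in week 8 alone 2606 and 362, with 2960 of those 2968 among the 5837. The all-gene median was 0.16 (0.00 for CAC and -0.17 for NCAC against Con). Rescaling moved it by 0.18 and gave 2177 rises and 2483 falls. The 10 largest rises were Mt2 at 4.33 (SE 0.63, adjusted p = 4.52e-07, limma), Serpina3n at 4.29 (SE 0.54, 1.85e-08), Serpina3m at 3.77 (SE 0.36, 2.09e-11), Ccl8 at 3.60 (SE 0.53, 5.04e-07), Hp at 3.57 (SE 0.63, 1.46e-05). With them came Saa1 at 3.53 (SE 0.54, 1.11e-06), Lcn2 at 3.44 (SE 0.43, 1.88e-08), the fetuin gene Fetub at 3.31 (SE 0.26, 6.22e-14), Cxcl13 at 3.29 (SE 0.63, 4.01e-05) and Pla2g5 at 3.25 (SE 0.36, 1.08e-09), each in 7 of 7 except Saa1 in 6 of 7. The 10 largest falls were Nnat at -4.18 (SE 0.92, 2.87e-04), Nmrk2 at -2.80 (SE 0.57, 1.05e-04), the leptin gene Lep at -2.23 (SE 0.68, 0.00652), Oxtr at -2.12 (SE 0.50, 5.75e-04), Mfap4 at -2.07 (SE 0.41, 8.08e-05). With them came Kera at -2.04 (SE 0.55, 0.00251), Chad at -2.04 (SE 0.61, 0.006), the natriuretic peptide receptor gene Npr3 at -1.96 (SE 0.30, 9.2e-07), the secretogranin gene Scg3 at -1.92 (SE 0.24, 1.22e-08) and Prr32 at -1.92 (SE 0.34, 1.31e-05), each in 7 of 7 except Nnat and Nmrk2 in 6 of 7. Lep (0.0709) and Oxtr (0.0681) did not pass in week 8 alone.

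Acute phase and STAT3 genes gave 18 rises of 21 in this comparison (17 rescaled, 17 in week 8 alone, 18 adjusted over the list alone, camera adjusted p = 3.64e-10, adjusted p = 0.244 with an estimated correlation). Among them were Stat3 at 1.39 (SE 0.12, 3.03e-12) and Bcl3 at 2.00 (SE 0.19, 2.09e-11). Glucocorticoid and FoxO targets gave 22 rises and 1 fall of 24 (18 and 1 rescaled, 17 and 0 in week 8 alone, 22 and 1 adjusted over the list alone, camera adjusted p = 1.87e-04, adjusted p = 0.738 with an estimated correlation). Among them was Fkbp5 at 2.63 (SE 0.47, 1.59e-05). Atrophy ubiquitin ligases gave 11 rises and 0 falls of 16 (5 and 2 rescaled, 8 and 0 in week 8 alone, 11 adjusted over the list alone, camera adjusted p = 0.0249, adjusted p = 0.738 with an estimated correlation). Fbxo31 rose by 1.96 (SE 0.28, 4.4e-07), Ubr2 by 0.79 (SE 0.13, 6.29e-06), Cblb by 0.81 (SE 0.15, 2.53e-05), Trim63 by 1.60 (SE 0.34, 1.87e-04), Fbxo32 by 1.31 (SE 0.31, 5.6e-04) and Fbxo30 by 0.50 (SE 0.15, 0.00668; 0.113 rescaled), each in 7 of 7 and past the threshold in week 8 alone. Respiratory chain genes fell in 50 of 61 cases (56 rescaled, 37 in week 8 alone, 52 adjusted over the list alone, median -0.44, camera adjusted p = 1.29e-40, adjusted p = 0.0471 with an estimated correlation). Among them were Cox7a1 at -1.46 (SE 0.18, 1.77e-08), Ndufc1 at -0.91 (SE 0.11, 8.95e-09) and Ndufa4 at -0.89 (SE 0.10, 2.41e-09). Sarcomere core genes gave 14 rises of 20 (7 rescaled, 7 in week 8 alone, 15 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.738 with an estimated correlation). Their median was 0.65 (-0.51 in NCAC against Con). Rises included Des at 1.17 (SE 0.18, 1.72e-06, 7 of 7), Ttn at 0.97 (SE 0.22, 3.2e-04, 6 of 7), Neb at 0.89 (SE 0.20, 3.42e-04, 6 of 7) and Unc45b at 0.82 (SE 0.16, 4.61e-05, 7 of 7).

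In the same comparison denervation response genes rose in 8 of 16 cases (4 rescaled, 4 in week 8 alone, 8 adjusted over the list alone, camera adjusted p = 0.381). Among them were Runx1 at 1.09 (SE 0.16, 5.84e-07), the acetylcholine receptor subunit Chrna1 at 0.99 (SE 0.19, 4.09e-05) and Musk at 1.31 (SE 0.26, 7.18e-05). Immediate early genes rose in 13 of 20 cases (11 rescaled, 10 in week 8 alone, 13 adjusted over the list alone, camera adjusted p = 0.00981, adjusted p = 0.738 with an estimated correlation). Among them was Junb at 1.84 (SE 0.29, 1.5e-06). Endothelial markers gave 8 rises and 1 fall of 12 (3 and 1 rescaled, 6 and 0 in week 8 alone, 8 and 1 adjusted over the list alone, camera adjusted p = 0.109). Among them were Esam at 0.94 (SE 0.12, 2.88e-08) and Pecam1 at 0.81 (SE 0.11, 2.4e-07), and these 6 genes were higher in 7 of 7. Adipocyte markers gave 1 rise and 2 falls of 13 (0 and 4 rescaled, 0 and 0 in week 8 alone by limma, 1 and 2 adjusted over the list alone, camera adjusted p = 0.0123, adjusted p = 0.738 with an estimated correlation). Macrophage markers gave 3 rises of 13 (2 rescaled, 1 in week 8 alone, 3 adjusted over the list alone, camera adjusted p = 0.923). Of the 15 panel genes 10 rose, the others besides those above being Cdkn1a at 1.00 (SE 0.34, 0.0148, 6 of 7), Gadd45a at 0.84 (SE 0.31, 0.0248, 6 of 7) and Myh4, a fast myosin, at 2.58 (SE 0.92, 0.0193, 7 of 7). Myh4 stood at 2040 TPM in CAC replicate 6 and at 5.53 to 23.6 TPM in the other CAC libraries, and was 1.52 without replicate 6. These 3 did not pass in week 8 alone (0.0826, 0.122 and 0.102). They lost their calls without CAC replicate 1 (Cdkn1a 0.0595, Gadd45a 0.0797), CAC replicate 6 (Gadd45a 0.0968, Myh4 0.096), NCAC replicate 3 (Myh4 0.0781) or NCAC replicate 4 (Gadd45a 0.0549, Myh4 0.0502), and Cdkn1a (0.072) and Gadd45a (0.117) after rescaling. Not past the threshold were Mstn (0.77, adjusted p = 0.0659, 6 of 7), Pdk4 (0.32, 0.525, 5 of 7), Myh7 (0.27, 0.456, 5 of 7), Myh2 (0.31, 0.5, 4 of 7) and Col1a1 (-0.55, 0.411, 4 of 7). Mstn passed without CAC replicate 1 (0.0352), 3 (0.0428) or 4 (0.0414), and Myh7 without CAC replicate 6 (0.0175).

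Both 8-week comparisons called 2902 genes in 1 direction, 2018 higher and 884 lower in CAC (774.1 and 156 for independent lists), with 2 opposite. Rescaled values gave 1462 and 1817, and week 8 alone 771 and 272. The CAC libraries enter both comparisons. In 100 simulations of unchanged groups 27 genes on average and 48 at most were called in both. Other splits of the libraries reached 2651. With the 7 CAC libraries divided into 3 and 4, 1 part per comparison, the 70 divisions gave 1050 to 2350 genes (median 1729.5). The covariance of the fold changes across genes was 0.1778, against 0.023 in the simulations. Genes are not independent replicates.

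**Figure D4:**
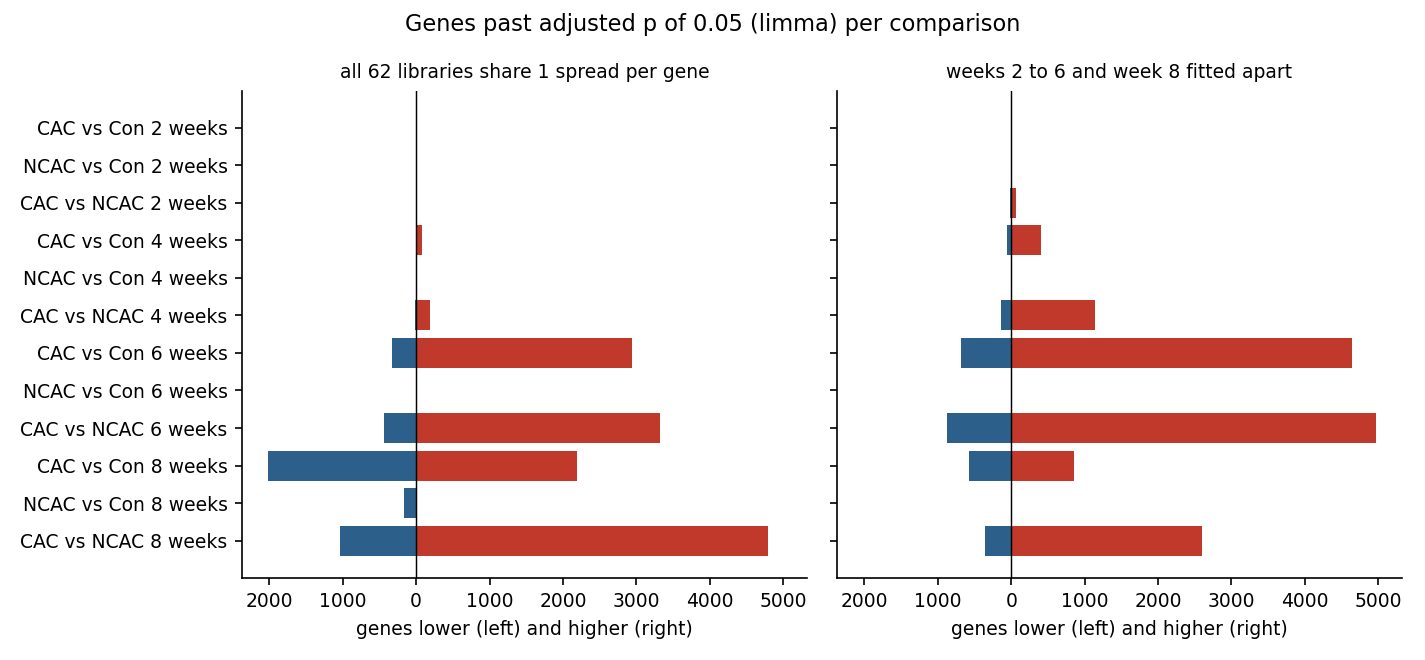
Genes past an adjusted p of 0.05 by limma (x axis, lower to the left and higher to the right) for the 12 comparisons within a week (y axis). The left panel is the fit with 1 spread per gene for all 62 libraries, and the right panel fits weeks 2 to 6 and week 8 apart. In the left panel CAC against Con gave 1, 84, 3269 and 4206 genes at 2, 4, 6 and 8 weeks, and NCAC against Con 1, 0, 0 and 175.

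The interaction of treatment and week tested whether the cachectic effect differed between 8 and 2 weeks. The log2 fold change of CAC against Con was shifted upward at 8 weeks for 266 genes and downward for 538, and for 448 and 520 after rescaling. Differences of 4.84 (SE 0.92, adjusted p = 8.09e-04, limma) for Cxcl13, 3.93 (SE 0.79, 0.00159) for Saa1 and 3.80 (SE 0.53, 1.5e-05) for Serpina3m were the largest upward. Values of -5.70 (SE 1.36, 0.00765) for Nnat, -3.29 (SE 0.73, 0.00478) for Oxtr and -3.04 (SE 0.84, 0.0213) for Nmrk2 were the largest downward. Serpina3n (3.26, SE 0.79, 0.00847), Mt2 (3.52, SE 0.93, 0.0155), Lcn2 (3.31, SE 0.63, 8.09e-04) and Sgk1 (1.89, SE 0.50, 0.0155) differed upward, and Cox7a1 (-1.23, SE 0.27, 0.00332) and Ndufb8 (-0.93, SE 0.18, 7.86e-04) downward. These genes lay on that side of the Con mean in 7 of 7 CAC libraries at 8 weeks, except Saa1 and Nnat in 6 of 7. Acute phase and STAT3 genes differed upward in 8 of 21 cases (16 adjusted over the list alone, camera adjusted p = 1.54e-13, adjusted p = 0.277 with an estimated correlation). Glucocorticoid and FoxO targets gave 8 upward and 1 downward of 24 (14 and 1 adjusted over the list alone, camera adjusted p = 3.47e-11, adjusted p = 0.32 with an estimated correlation). Respiratory chain genes gave 23 downward of 61 (6 rescaled, 35 adjusted over the list alone, camera adjusted p = 1.52e-16, adjusted p = 0.32 with an estimated correlation). The count was 514 without CAC replicate 1 of week 2, 507 without Con replicate 2 and 1359 without CAC replicate 3 of week 8. A fit of the 4 groups compared gave 4 acute phase and STAT3 genes and 2 glucocorticoid and FoxO targets upward and 3 respiratory chain genes downward. It gave 296 genes in all, in which Saa1 (0.0587), Nmrk2 (0.0813) and Mt2 (0.0515) did not pass.

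The same test between 6 and 2 weeks, added after seeing the data because week 8 stood apart, gave 21 upward and 3 downward shifts, and 23 and 9 after rescaling. Mt2 differed by 4.29 (SE 0.96, adjusted p = 0.0443, limma), Serpina3n by 3.71 (SE 0.82, 0.0407), Tmem252 by 2.57 (SE 0.48, 0.0252) and Osmr by 1.21 (SE 0.27, 0.0407), and the acetylcholine receptor subunit Chrna2 by -1.78 (SE 0.40, 0.0444) and Ociad2 by -1.28 (SE 0.30, 0.0462), in 5 of 5 CAC libraries each. The count was 3 without Con replicate 1, 3 or 5 or CAC replicate 2 of week 2, 5 without CAC replicate 4 of week 2 or Con replicate 4 of week 6, 8, 1 and 2 without Con replicates 1, 2 and 3 of week 6, and 47 without CAC replicate 5 of week 6. It was 0 without Con replicate 2 or 4 or CAC replicate 1 or 5 of week 2, and without Con replicate 5 or CAC replicate 1, 2 or 4 of week 6. A fit of the 4 groups compared gave 338 genes, among them all 24. None of the 6 genes kept its call in all 20 fits without 1 library. Without CAC replicate 1 of week 6 the adjusted p was 0.154 for Mt2, 0.136 for Serpina3n, Osmr and Chrna2, 0.0852 for Tmem252 and 0.224 for Ociad2.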

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

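The tests of a lower share of muscle fibres, of separate processing and of the mitochondrial share of TPM, the fit of week 8 alone and the comparison of 6 with 2 weeks were chosen only after the results were seen. In 4 of 37 groups of a gene's values, 1 library lay far from the others. Serpina3n in CAC replicate 3 of week 8 stood at 88.7 TPM against 642 to 1420 TPM in the others, and this library was also low in Mt2 and Fkbp5 and high in haemoglobin. Mt2 in NCAC replicate 2 of week 8 stood at 21.3 TPM against 68.8 to 91.8 TPM, Nnat in Con replicate 1 of week 8 at 45.1 TPM against 196 to 292 TPM, and mt-Atp8 in NCAC replicate 5 of week 8 at 5960 TPM against 17700 to 26200 TPM. Chance gives such a library in about 1 of 20 groups. All 4 were from week 8, as were 21 of the 37 groups.

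The CAC effect differed between 8 and 2 weeks in 804 genes by the interaction test. It was larger by 4.84 for Cxcl13, 3.93 for Saa1, 3.80 for Serpina3m, 3.52 for Mt2, 3.31 for Lcn2, 3.26 for Serpina3n and 1.89 for Sgk1 on the log2 scale. It lay lower at -5.70 for Nnat, -3.29 for Oxtr, -3.04 for Nmrk2, -1.23 for Cox7a1 and -0.93 for Ndufb8. Between 6 and 2 weeks 24 genes differed, by 4.29 for Mt2, 3.71 for Serpina3n, 2.57 for Tmem252, 1.21 for Osmr, -1.78 for Chrna2 and -1.28 for Ociad2.

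Other splits of the same libraries into groups of the same sizes were fitted, 100 per result with the real split included. As many genes as the real split came from 1 of 100 for CAC against Con at 4 weeks (84 genes, highest other 27), CAC against NCAC at 4 weeks (200, 139), CAC against Con at 6 weeks (3269, 2777), CAC against NCAC at 6 weeks (3760, 3676), CAC against Con at 8 weeks (4206, 3456) and CAC against NCAC at 8 weeks (5837, 5745). The same was found for Con at 8 against 2 weeks (8115, 5903), the effect at 8 less 2 weeks (804, 411) and the genes in both 8-week comparisons (2902, 2651). The lowest possible share is 1 of 100, so chance is unlikely but not excluded. The share was 1 of 100 for NCAC against Con (1 gene, highest other 0 by limma) and CAC against NCAC (7, highest other 1) at 2 weeks. It was 4 of 100 for CAC against Con at 2 weeks (1, highest other 28) and the effect at 6 less 2 weeks (24, highest other 2004). Leaving out 1 library brought each of these 4 counts to 0 by limma, so chance stays open for them. It cannot be excluded for NCAC against Con at 8 weeks (175, 32 of 100, highest other 5564). Splits that call several times the real count, up to 28, 2004 and 5564 genes, point to a structure of the samples, whose nature was not tested. NCAC against Con gave 0 genes by limma at 4 weeks (55 at unadjusted p under 0.05, highest other 2) and at 6 weeks (130 at unadjusted p under 0.05, highest other 1). There 100 of 100 splits give as many by construction, so the splits decide nothing.

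The 8-week libraries stood apart in every treatment. A lower share of muscle fibres would raise the markers of all other cells alike, but the Schwann cell median of Con at 8 against 2 weeks was -0.545 beside a macrophage median of 3.37, which argues against it as the whole cause. After a trend on gene length was removed, 55.4% of the called genes with a length (4356 of 7859) kept their call and direction, and the macrophage median went from 3.37 to 2.67, which argues against length bias as the whole cause, while the ribosomal protein median went from 1.34 to 0.79, so part of that rise went with gene length. Separate processing cannot be told apart from time, since 16 of the 17 libraries of week 8 lay beyond all earlier ones and no label gives a batch. Time after injection stays open as a biological explanation, untested, and the labels give an age of 2 months in every group.

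At 6 weeks CAC rises outnumbered falls. No single library made the excess, since the share of rises was 90% and stayed at 87.8% to 92.5% without each. Fewer mitochondrial transcripts may raise the TPM of other genes. With TPM over those genes alone the median of all genes went from 0.16 to 0.043, with 973 rises and 591 falls. Part of the excess went with these transcripts. The rest is undecided. The cachectic tumour stays open as a biological explanation.

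Falls with NCAC at 8 weeks could come from scaling or spread. Rescaling kept 19 of the 175 calls and took the median of the falls from -0.40 to -0.24. It centres the median of all genes and so decides nothing. With TPM over genes outside the mitochondrial genome 8 passed (4 higher, 4 lower), and the median of all genes went from -0.17 to -0.13. The fit of week 8 alone kept 0 by limma (1205 of all genes at unadjusted p under 0.05, median SE 0.14 against 0.10). It found 20.9% of simulated changes of 0.5 and would lose real changes too. The fit of all libraries found 56.7% but called 382 unchanged genes, so spread could explain the 175. Scaling stays undecided, and an NCAC effect stays open as a biological explanation.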

How the results depend on the processing

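The fits without week 8, of week 8 alone and without the high-Myh4 libraries, and all results for 6 less 2 weeks, were chosen after seeing the data. Counts of NCAC against Con at 4 weeks stayed 0 by limma under each alternative (55 at unadjusted p under 0.05 with all libraries), and Con at 8 against 2 weeks stayed within 1.5 times its count of 8115. Of 251 results for named genes 85 changed their call under at least 1 alternative, and 8 turned direction. For the counts given here the cause was not tested, except that fewer libraries or genes enter some fits by construction.

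With a pseudocount of 0.1, NCAC against Con at 8 weeks gave 49 genes. With no filter, CAC against Con, NCAC against Con and CAC against NCAC at 2 weeks gave 3, 3 and 14, CAC against NCAC at 4 weeks 133, NCAC against Con 1 at 6 weeks and 347 at 8 weeks, and 6 less 2 weeks 4. After median-of-ratios rescaling, NCAC against Con gave 0 at 2 weeks by limma (832 at unadjusted p under 0.05) and 65 at 8 weeks, and CAC against Con at 6 weeks 1821. The log2 fold changes of Pdk4 and Myh2 in CAC against Con at 6 weeks, neither past the threshold, turned to -0.16 and -0.19. The camera direction turned for proteasome subunits and macrophage markers in CAC against Con at 8 weeks, where the mean difference from other genes was 0.034 and -0.0082, and for erythroid markers in Con at 8 against 2 weeks (0.8474).

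Fits of the compared groups alone gave 0 genes for CAC against Con at 2 weeks (by limma, 1260 at unadjusted p under 0.05). CAC against NCAC gave 4, with 0 of the main 7. In this order the fits gave 21 and 27 at 4 weeks, and 1680 and 1594 at 8 weeks. They gave 1 and 0 (by limma, 2101 at unadjusted p under 0.05) for NCAC against Con at 6 and 8 weeks, 296 for 8 less 2 weeks, 338 for 6 less 2 weeks and 775 in both 8-week comparisons. On residuals, in none of 12 comparisons did every pair of libraries with the same replicate number correlate above 0.1, and in 9 of 60 pairs the library with the same number was the best match, so the libraries share only a number. With that number as a replicate block, CAC against Con at 2 weeks gave 2 and NCAC against Con at 8 weeks 1102, and Myh7 and Myh4 in CAC against Con at 8 weeks turned to 0.20 and -0.14. Quality weights gave 18, 4 and 652 for CAC against Con, NCAC against Con and CAC against NCAC at 2 weeks, 257 and 888 for CAC against Con and against NCAC at 4 weeks, 5745 for CAC against Con at 6 weeks, 3067 for NCAC against Con at 8 weeks, 1546 for 8 less 2 weeks and 1224 for 6 less 2 weeks, and Myh2 in CAC against Con at 6 weeks turned to -0.059.

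Without week 8, CAC against Con gave 0 (by limma, 861 at unadjusted p under 0.05), 462 and 5317 at 2, 4 and 6 weeks, and CAC against NCAC 73, 1277 and 5842. Week 8 alone gave 1430, 0 (by limma, 1205 at unadjusted p under 0.05) and 2968 for CAC against Con, NCAC against Con and CAC against NCAC, and 1043 in both. Without the high-Myh4 libraries (CAC replicate 4 of week 2, NCAC replicate 3 of week 6, CAC replicate 6 of week 8), CAC against Con and against NCAC at 2 weeks gave 0 by limma (267 and 1024 at unadjusted p under 0.05), NCAC against Con at 8 weeks 1271 and 6 less 2 weeks 6, and Myh7 in CAC against Con at 8 weeks turned to 0.018.

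Without each library, CAC against Con at 2 weeks ran from 0 to 2, NCAC against Con 0 to 1 and CAC against NCAC 0 to 14. At 4 weeks CAC against Con ran from 27 to 199 and CAC against NCAC from 40 to 568. At 6 weeks they ran from 1293 to 4454 and from 2031 to 4824, and NCAC against Con at 4 and 6 weeks from 0 to 0. At 8 weeks CAC against Con ran from 3481 to 4827, NCAC against Con from 8 to 1938, CAC against NCAC from 5140 to 6514 and both from 2317 to 3345. The range was 507 to 1359 for 8 less 2 weeks, 0 to 47 for 6 less 2 weeks and 7201 to 8102 for Con. Log2 fold changes that turned in some of these fits ran in CAC against Con at 6 weeks from -0.16 to 0.21 for Pdk4, -0.21 to 0.25 for Myh2 and -0.015 to 0.51 for Myh4. In CAC against Con at 8 weeks they ran from -0.042 to 0.38 for Pdk4, -0.54 to 0.018 for Myh7 and -0.090 to 0.37 for Myh2, and in CAC against NCAC at 8 weeks from -0.075 to 0.69 for Myh2. None of these genes passed in these comparisons with all libraries.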

Other observations

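Clock and growth factor genes changed in both directions at 8 weeks. In CAC against Con, circadian clock genes gave 4 rises and 2 falls of 18 (2 and 1 in week 8 alone, 4 and 2 adjusted over the list alone, camera adjusted p = 0.605). Nfil3 rose by 2.41 (SE 0.45, adjusted p = 4.33e-05, limma, 6 of 7) and Cry1 by 0.63 (SE 0.14, 3.27e-04, 7 of 7). Bhlhe41 fell by 0.99 (SE 0.22, 4.74e-04, 6 of 7). Times of day are not given in the sources used here.

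Growth factor and myostatin signalling genes gave 6 rises and 8 falls of 23 (5 and 3 in week 8 alone, 6 and 8 adjusted over the list alone, camera adjusted p = 0.895). Igfbp3, a binding protein of insulin-like growth factors, rose by 1.90 (SE 0.31, adjusted p = 5.4e-06, limma) and the BMP antagonist gene Nog by 1.08 (SE 0.22, 1.84e-04). Igfbp5 fell by 1.75 (SE 0.31, 2e-05) and Smad6 by 0.70 (SE 0.13, 5.29e-05), and these 4 genes moved that way in 7 of 7 libraries. Of 8 tested neutrophil markers 5 rose and 1 fell (4 and 0 in week 8 alone, 5 and 1 adjusted over the list alone, camera adjusted p = 0.0152, adjusted p = 0.713 with an estimated correlation). Interferon response genes gave 7 falls of 28 (0 in week 8 alone by limma, 5 adjusted over the list alone, camera adjusted p = 0.0224, adjusted p = 0.968 with an estimated correlation).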
